A study of Homo sapiens with 2 samples.

How the data were processed

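The study measured messenger RNA in MCF7 cells, an established luminal breast cancer line, that carry a retroviral construct from which doxycycline switches on ΔNp63α, the p63 isoform that lacks the amino-terminal transactivation domain. Per the labels, 1 culture received no doxycycline (uninduced) and 1 was treated for 48 hours (induced). Total RNA was extracted with a miRNeasy kit, amplified to amino allyl RNA, coupled to Cy5 and hybridised to 1-colour Toray arrays, per the labels' protocols. Each group held 1 array, so there were no replicates, no spread within a group and no test of a difference, and group and array cannot be told apart. The number of arrays limits the precision of every value.

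The spot values are median intensities at 635 nm, not background-subtracted and not normalized, and the values of 3 scanner gains were merged by straight lines, per the file headers. Each array held 27456 spots, of which 24460 were gene probes and 2680 were blank. The authors' own processed values are intensities on a linear scale in the deposited value table, and how they were made is not given in the sources used here. The brighter of them were set against the spot values. Each closely equalled the spot value minus a mean over blank spots (5% trimmed on each side), times 1 factor per array, 0.556 on both. The factor was not computed for dimmer ones. The median of each array's deposited intensities was 25.0, and spots not above the blank mean plus 2 SD had no value. This limit left 4 probes of the uninduced and 0 of the induced array unexplained. The deposited intensities are therefore linear values with a common median of 25.0, not centred on 0 and not on a log scale.

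The values described here were computed from the spot intensities with limma 3.58.1 in R 4.3.3. Background was corrected by normexp fitted on the blank spots with an offset of 50, the 2 arrays were quantile normalized without control and blank spots, and log2 was taken. This departs from the plan in 1 point. The plan, like the lists, thresholds, alternatives and rules for naming genes, was set before the data were examined, and named normexp on the local background column with the same offset. That column followed the signal of the spot itself, with a Spearman correlation across spots of 0.92 on the uninduced and 0.95 on the induced array. In the brightest 10% of probes it amounted to a median of 46.7% and 64.7% of the spot signal. Around dark spots it had a median of 34.8 beside bright spots and 34.2 beside dark ones on the uninduced array, and 33.1 and 32.3 on the induced array, so neighbouring spots added little to it. The change was made after the spot and background columns, including single spots under both corrections, had been examined and before differences were computed for genes. The planned setting was run as an alternative, and its values are given beside the lists it moved across the random range and beside the named genes that then changed sign or no longer passed a log2 difference of 1.

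A probe was detected on an array when its spot exceeded the mean plus 2 SD of the blank spots, with 2.5% left out on each side. These limits were 45.784 on the uninduced and 45.773 on the induced array. On the uninduced array 20712 probes (84.7%) were detected and on the induced array 21018 (85.9%). Over detected probes the median signal above the blank mean was 48.5 and 48.4, so many probes lay close to the offset. Among the 48 positive control spots, spots of the same control had a pooled SD of 0.145 and 0.17 on the log2 scale within the arrays. 1 probe with a quality mark on the induced array was left out, which left 24459.

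Names came from the platform annotation, brought up to date through an NCBI RefSeq gene table. In it 20235 probes had 1 symbol, 0 had several and 4224 had none and stayed unnamed. Of 17621 symbols 14997 were current, 2538 were updated and 86 were kept as they stood, giving 17559 genes. No coordinates are given, because no genome build was named for the probes. A gene with several probes (2559 genes) was represented by its brightest, chosen anew under each alternative. Analysis covered the 15787 genes detected on at least 1 array.

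Differences are induced minus uninduced on the log2 scale of normalized intensity with the offset included, which understates the differences of dim genes. A gene was counted as higher or lower by size alone, at an absolute log2 difference of at least 1. For genes detected on 1 array the fold is a lower bound, against the lowest normalized signal of a detected probe or the gene's own, whichever was higher. For 27 gene lists the median difference of the detected members was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. The central 95% of those medians served as the reference, as a description of these 2 arrays. Named by rule were TP63, TP53 and TP73, the 12 genes with the largest positive and the 12 with the largest negative difference among those detected on both arrays, and the 5 genes per array with the largest lower bound among those detected on 1. For each list up to 3 members at either end were named. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

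The steps were tested on simulated data made for this comparison from the 24459 probes, with spot noise of 0.145. Of probes changed 4-fold upwards, 12 had a signal above blanks of at least 200. These came out at a median log2 difference of 1.795 with 100% past 1, and the 38 dimmer ones at 0.924 with 44.7% past 1. Of probes changed 2-fold upwards, the 10 brighter came out at 0.984 with 40% past 1 and the 40 dimmer at 0.334 with 0% past 1. The recovered medians were smaller downwards, with few bright probes in each class. Probes lowered 4-fold came out at -1.715 with 100% past 1 (13 bright probes) and at -0.452 with 24.3% (37 dim probes). Probes lowered 2-fold came out at -0.822 with 26.7% past 1 (15 bright probes) and at -0.135 with 0% (35 dim probes). None (0) of 24259 unchanged probes passed 1. Both simulated arrays were made from the uninduced array with spot noise alone. That count therefore leaves out differences between hybridisations, labellings and cultures. Of 20 simulated lists without a shift 1 lay outside the central 95%, and of 20 lists shifted by 0.3 on the log2 scale 20 did. Their members were drawn at random from the same genes as the reference lists. Lists whose members vary together were therefore not tested, and for them the range may be too narrow. Each simulated list had 30 members. Some of the 27 lists had wider random ranges, such as -0.29 to 0.3 for the histone genes and -0.31 to 0.31 for the reference genes. A shift of 0.3 need not stand out in those. The alternatives were other background corrections (none, plain subtraction of the local background or of the blank mean, offset 16, and the planned local background setting), median, 75th percentile and loess scaling, the authors' deposited intensities, no filter on detection, only probes above the median signal, the mean of a gene's probes, 1.5-fold and 4-fold thresholds, and members detected on both arrays. Subtraction of the blank mean was added after the data were seen.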

Results

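Gene expression was profiled on 2 microarrays, 1 of uninduced MCF7 cells with an inducible ΔNp63α construct and 1 of the same cells after 48 hours of doxycycline. The median spot intensity of the gene probes was 73.0 on the uninduced and 75.1 on the induced array. Of 15787 genes detected on at least 1 array, 15023 were detected on both, 478 on the induced array alone and 286 on the uninduced array alone. Across genes the normalized values of the arrays had a Spearman correlation of 0.96, where genes are not independent replicates. The comparison asks how the transcripts of a luminal breast cancer line differ once ΔNp63α, the p63 isoform typical of basal and stratified epithelium, is switched on. There were no replicates, so every difference below is between 2 arrays and has no replicate check.

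In the induced array the genes of cell division were lower almost throughout. The 31 detected G2/M and mitosis genes had a median log2 difference of -2.15, and the 38 detected DNA replication genes one of -1.95. Of 32 p53 target genes 11 were higher by at least 1, led by BTG2 with a log2 difference of 3.97 and CDKN1A, the cyclin-dependent kinase inhibitor p21, with 2.82, and 11 lay below 0. Of 26 basal epithelial genes 4 were higher by at least 1, among them LAMB3, a chain of laminin-332 (2.64), and PERP, a desmosome component (2.0). Of 30 oestrogen response genes 7 were lower by at least 1, led by TFF1 (-2.53), and of 21 luminal genes 3 were, among them the transcription factors XBP1 (-2.40) and SPDEF (-2.09), while the luminal median of -0.10 lay inside the range of random lists. Under the planned local background correction the p53 target median of 0.34 was 0.08, inside the range of random lists, and CDKN1A and SPDEF changed sign, at -0.47 and 0.06.

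TP63 itself, the induced gene, was represented by 1 probe (H300019931). Its spot intensity was 45.6 on the uninduced array, below the detection limit, and 258.7 on the induced array. The authors' deposited intensities of this probe were 1.3 and 119.7. On the normalized scale the log2 difference was 2.35, at least 5.1-fold higher in the induced array. With the planned correction by the local background column, which followed the signal of the spots themselves, it was 0.04. Whether the probe lies within the expressed construct is not known here, so it checks the labels only as far as it reports that transcript. TP73, the closest relative of TP63, was near background on both arrays, with deposited intensities of 9.95 in the uninduced and 2.9 in the induced array and a log2 difference of -0.32. TP53 is not analysed here because none of the named probes had its symbol.

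By size, 326 genes (2.1%) were higher and 442 (2.8%) were lower by a log2 difference of at least 1, and 15019 lay between. At 4-fold the counts were 44 and 97. In the authors' deposited intensities, which have no offset, 950 genes were higher and 957 lower of 15338 with a value on both arrays, and these included 317 of the 326 and 441 of the 442. With the planned local background correction the counts were 394 and 553, which shared 130 of the higher and 163 of the lower genes with those above. Differences under the 2 corrections correlated across genes with a Pearson r of 0.48. For the 1774 genes with 2 detected probes, the probes' differences correlated with an r of 0.72 across genes, which corresponds to an SD of 0.25 per probe.

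**Figure D1:**
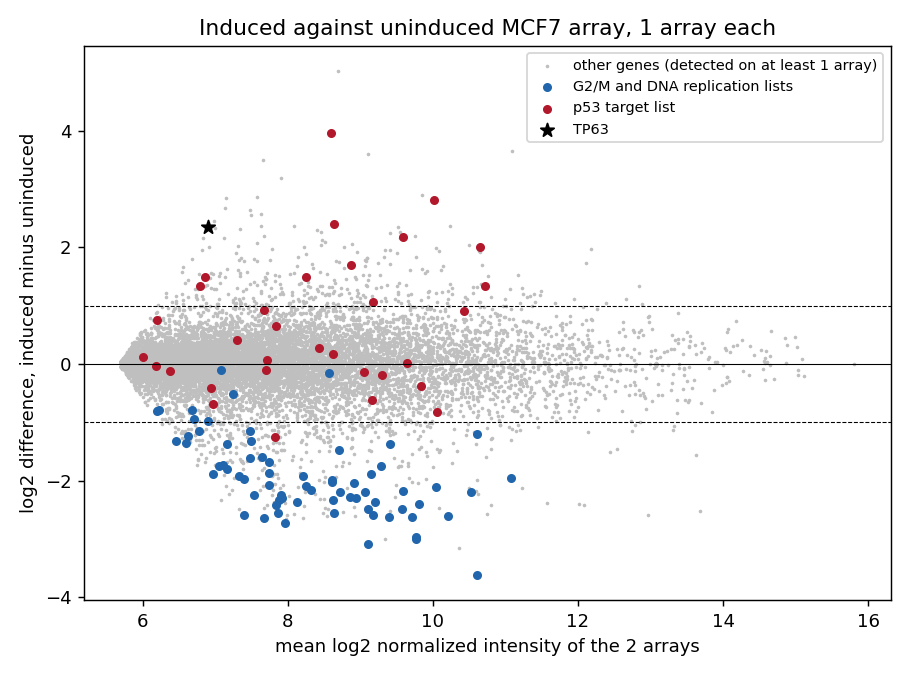
Log2 difference (induced minus uninduced) of each of the 15787 detected genes against its mean log2 normalized intensity over the 2 arrays, with dashed lines at a difference of 1 in either direction. G2/M and DNA replication genes (blue) lie below 0 at every brightness, p53 target genes (red) lie mostly above 0, and TP63 is marked by a star at 2.35.

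The 12 genes with the largest positive differences included several regulators of growth and transcription. BTG2, an antiproliferative p53 target, had deposited intensities of 26.2 in the uninduced and 790.0 in the induced array. ID3, an inhibitor of basic helix-loop-helix transcription factors, differed by 3.65 (322.7 and 4289.8), and FOS, a subunit of the AP-1 transcription factor, by 3.19 (16 and 359.0). PNRC1, a nuclear receptor coactivator, differed by 2.89 at its brightest probe and by 1.16 at its other probe. STK3, a kinase of the Hippo pathway, differed by 2.84, from a spot at the detection limit on the uninduced array. CDKN1A differed by 2.82 (194.6 and 1418.1). Among genes of adhesion and secretion, MPZL2, an epithelial adhesion protein, differed by 3.60, SERPINF1, a secreted serpin, by 3.50, and LAMB3 by 2.64. TMEM40 (2.87) and TRIM54 (2.67) completed the group together with UGT1A8, a glucuronidation enzyme, which had the largest difference of all on the scale with the offset, at 5.02. In the authors' deposited intensities STK3 differed by more, at 6.97 against 6.66 for UGT1A8. The UGT1A genes share exons, so the value of UGT1A8 is uncertain, and the other probe of that name differed by 1.13. With the local background correction FOS was at -0.28 and CDKN1A at -0.47, and STK3 was at 0.01.

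All 12 genes with the largest negative differences act in DNA synthesis or cell division. RRM2, a subunit of ribonucleotide reductase, differed by -3.62 at its brightest probe, with deposited intensities of 3045.6 in the uninduced and 213.5 in the induced array, but by -0.09 at its other probe. CDC2, the older name under which the annotation lists a mitotic kinase, differed by -3.16. The name was kept because it is a synonym of more than 1 current gene. The cyclins CCNA2 (-3.09), CCNE2 (-2.65) and CCNB2 (-2.63) were lower, as were thymidine kinase TK1 (-3.01) and the replication factors GINS2 (-2.96) and CDC45 (-2.73). CDCA8 (-3.01), SPC25 (-2.66), KIFC1 (-2.65) and UBE2C (-2.62), which act in chromosome segregation and mitotic exit, made up the rest. Under the local background correction each of these 12 genes was still lower, and the differences of CCNE2 (-0.28), CDC45 (-0.70), CCNB2 (-0.80) and SPC25 (-0.90) then lay within 1.

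**Figure D2:**
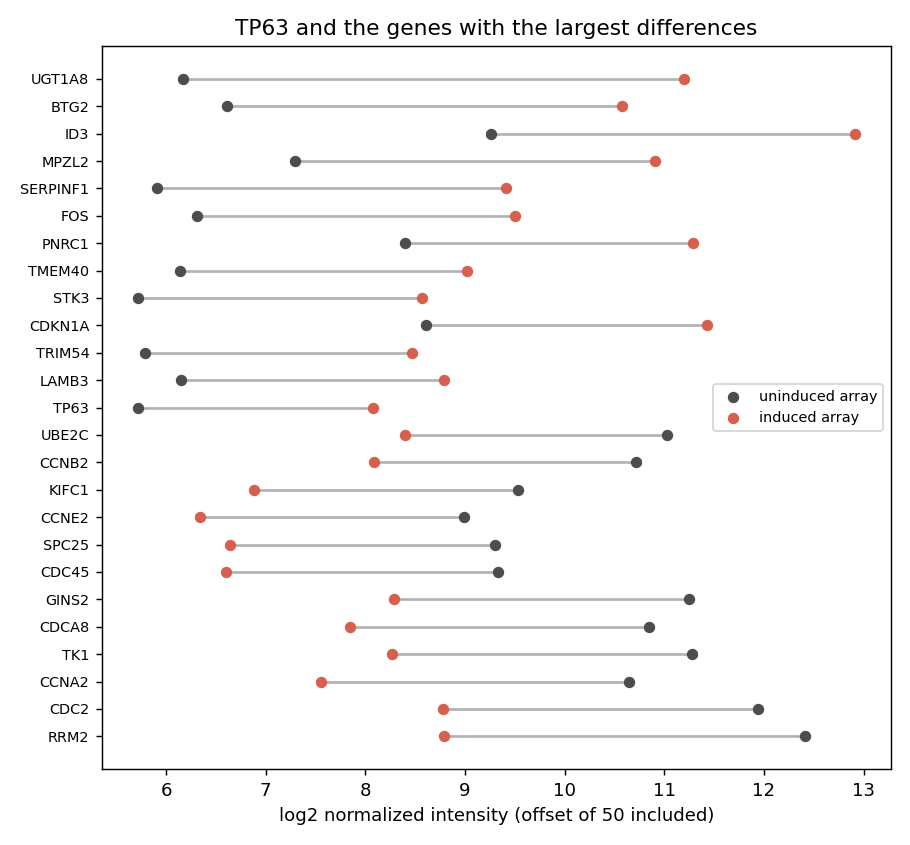
Log2 normalized intensity, offset of 50 included, of TP63 and of the 12 genes with the largest positive and the 12 with the largest negative differences on the uninduced (grey) and induced (red) array, with a line joining the 2 values of a gene. UGT1A8 spans the longest distance upwards (5.02) and RRM2 the longest downwards (-3.62).

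The cell cycle lists stood farthest from random lists. Of the G2/M and mitosis genes 29 of 31 were lower by at least 1 and 0 were higher, and the median lay below all 10000 random lists (percentile 0.00). On the scale with the offset the kinase NEK2 (-0.78) and the cytokinesis protein ANLN (-0.81), both dim, differed least, but not in the authors' deposited intensities (-2.68 and -2.92). They were followed by the phosphatase CDC25C (-1.24, and -0.71 with the local background correction). Of the DNA replication genes 32 of 38 were lower by at least 1 and 0 were higher, again at percentile 0.00. Cyclin E1, CCNE1 (-0.10), the clamp loader subunit RFC1 (-0.15, and 0.08 with the local background correction) and E2F1 (-0.51), a transcription factor of S phase genes, differed least on the scale with the offset. Together the lists had 69 detected members, of which 61 were lower by at least 1, and these made up 13.8% of all genes lower by that size. Both medians stayed below the random range under all 13 alternatives, between -2.91 and -1.57 for G2/M genes and between -2.41 and -0.75 for replication genes.

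Replication-dependent histone genes did not go with them. All 9 with a probe were detected, and 2 were higher by at least 1, H4C8 (1.78) and H2AC6 (1.59), and 0 lower. Their median difference was 0.48, at percentile 99.69 of random lists. H2BC21 differed by 0.78 and H1-5, a linker histone, by -0.69 (-2.32 in the authors' deposited intensities). H4C8 was at 0.57 and H2BC21 at -0.49 with the local background correction. Near-identical copies of these genes can bind the same probe, so single histone values are uncertain.

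Of 32 detected p53 target genes 11 were higher by at least 1 and 1 was lower. Their median was 0.34, at percentile 99.99. SESN1, a stress-induced inhibitor of mTORC1 signalling, differed by 2.39 after BTG2 and CDKN1A. AEN, an exonuclease, was lower by that size at -1.25, and the kinase PLK2 (-0.82) and the secreted factor GDF15 (-0.69) lay below 0 too. The median lay above the random range under 12 of 13 alternatives, at up to 0.63, and was 0.08, inside it, with the local background correction, where AEN was at -0.90.

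With the correction on blank spots, genes described as p63 targets and genes of basal and stratified epithelium had smaller medians than the p53 targets. This order was not tested. Medians of random lists matched on signal also spread less for the p63 list (-0.05 to 0.07) and the basal list (-0.05 to 0.05) than for the p53 list (-0.13 to 0.16). Genes of that brightness thus differ less on the scale with the offset, so the sizes of the medians cannot be compared directly. With the local background correction the p53 target median was 0.08, inside the random range, while the basal list stayed above it. Of 37 detected p63 targets 4 were higher by at least 1 and 1 was lower, with a median of 0.09 at percentile 99.53. PERP (2.0), the glutathione peroxidase GPX2 (1.76) and the Notch ligand JAG1 (1.62) led, and HELLS, a chromatin remodeller (-1.23), hexokinase HK2 (-0.70) and fatty acid synthase FASN (-0.68) were at the other end. With the local background correction GPX2 was at -0.26, JAG1 at -0.27, HELLS at -0.18 and FASN at 0.60. The list's median was 0.03 with that correction and lay inside the random range under 6 of 13 alternatives. Of 26 basal genes 4 were higher by at least 1 and 0 lower, with a median of 0.10 at percentile 99.92 that lay inside the random range under 4 of 13 alternatives. SFN, the 14-3-3 protein sigma, differed by 1.34 (0.87 with the local background correction) after LAMB3 and PERP. The lowest members, the keratins KRT6A (-0.07) and KRT5 (-0.05) and the hemidesmosome collagen COL17A1 (-0.05), had values near 0. The keratins KRT15, KRT14 and KRT17 were at 0.75, 0.26 and 0.12. The basal list shares 6 listed members with the p63 list and 2 with the p53 list, and the p53 and p63 lists share 2.

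Cell adhesion and integrin genes had a median of 0.14 at percentile 99.59, with 2 of 26 members higher by at least 1 and 1 lower. The laminin chain LAMB1 (1.62) and the integrins ITGAV (1.22) and ITGB4 (0.80, or 1.89 in the authors' deposited intensities) were highest. ITGB5 (-1.32), CD151 (-0.40) and ITGA5 (-0.31) were lowest. ITGAV was at -0.13, LAMB1 at 0.74 and ITGB5 at -0.87 with the local background correction, under which the median of 0.09 lay inside the random range, as it did in the authors' deposited intensities. Of 21 cornified envelope genes 1 was higher by at least 1, S100A8, and 1 lower, the protease inhibitor CSTA (-1.96, and -0.88 with the local background correction). Their median was 0.01, at percentile 68.38, and SERPINB5, the serpin maspin, differed by 0.47, or by 2.74 in the authors' deposited intensities (2.2 and 14.4).

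Of 30 detected oestrogen response genes 7 were lower by at least 1 and 2 were higher, with a median of -0.19 at percentile 0.65 that lay inside the random range with plain local subtraction (-0.24, percentile 2.51). TFF1, the trefoil factor that oestrogen induces in MCF7 cells, had deposited intensities of 16429.7 in the uninduced and 2972.2 in the induced array. The receptor tyrosine kinase RET differed by -1.64. FHL2 (1.82) and the insulin receptor substrate IRS1 (1.29) were higher. RET was at -0.68 and IRS1 at 0.34 with the local background correction. Of 21 luminal epithelial genes 3 were lower by at least 1, XBP1, SPDEF and AGR2 (-1.23, and -0.46 with the local background correction, where another probe was brightest and the probe used here was at -0.25), and 1 was higher, the keratin KRT80 (1.08, but -0.05 with the local background correction and 0.53 as the mean of its probes). ELF3, an epithelial transcription factor, differed by 0.67. The luminal median of -0.10, at percentile 13.30, lay inside the random range, and below it with the local background correction (-0.47).

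Cholesterol and fatty acid synthesis genes had a median of -0.62 at percentile 0.00, with 7 of 24 lower by at least 1 and 1 higher. The desaturases SCD (-1.67) and FADS1 (-1.18) and the squalene epoxidase SQLE (-1.27) were lowest, with SCD at -0.71 under the local background correction, and the sterol desaturase SC5D (1.79) was highest. Among 17 unfolded protein response and chaperone genes 3 were lower by at least 1 and 0 higher, with a median of -0.35 at percentile 0.18. These were XBP1, which is also in the luminal and oestrogen lists, and the endoplasmic reticulum proteins CRELD2 (-1.75) and SDF2L1 (-1.47). Both lists kept their place below the random range under all 13 alternatives. Glycolysis and hypoxia genes had a median of -0.20 at percentile 0.52, with 1 of 28 higher and 1 lower by at least 1, the glucose transporter SLC2A1 (1.51) and the aldolase ALDOA (-1.07). The enolase ENO1 differed by -0.62 (0.55 with the local background correction). The list's median was -0.01 with that correction, 0.05 when the local background was subtracted, -0.20 with median scaling and -0.15 with 75th percentile or loess scaling, inside the random range in all 5. Under these 3 scalings and in the authors' deposited intensities ALDOA lay within 1, between -0.97 and -0.91.

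Ribosomal protein genes had a median of 0.29 at percentile 99.67, with 0 of 27 members past 1 in either direction. RPL32 (0.96), RPL10 (0.88) and RPL5 (0.81) were highest and RPS6 (-0.23) was lowest, with values between 0.02 and 0.08 under the other scalings and in the authors' deposited intensities. The list's median lay inside the random range with the local background correction (0.10, percentile 58.04) and with plain local subtraction (0.21, percentile 75.57). The 14 common reference genes had a median of -0.32 at percentile 2.11, with tubulin TUBB (-1.97) lowest, YWHAZ (-0.67) and HPRT1 (-0.67) next and B2M (0.76) highest. That median was inside the random range under 7 of 13 alternatives and at 0.01 with the local background correction, under which YWHAZ was at 1.37. These genes were used only as a list, and none served as a scale.

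The remaining 12 lists, besides the luminal and cornified ones, had medians inside the random range. Notch pathway genes had a median of 0.04 at percentile 90.49 with JAG1 higher by at least 1, and HES4 differed by -0.97. Wnt and Hedgehog genes were at 0.00 (percentile 52.85) with DKK1, a secreted Wnt antagonist, at 2.58 and the receptor FZD5 at 1.5. DKK1 was at 0.27 and FZD5 at -0.51 with the local background correction. Mesenchymal genes were at 0.00 (percentile 48.46) with 0 of 20 past 1, and TGFBI (0.50), ITGA5, FN1 (-0.26, or -1.97 in the authors' deposited intensities) and VIM (-0.21) at their ends. Interferon response genes had a median of -0.02 (percentile 19.64) with IRF1 at 1.03 (0.14 with the local background correction), and inflammatory genes one of 0.01 (percentile 68.35) with NFKBIA at 1.07, which lay between 0.91 and 0.98 with median or 75th percentile scaling and in the authors' deposited intensities. Integrated stress response genes had a median of -0.10 (percentile 5.45) with DDIT4 (1.76) and SESN2 (1.70) higher and WARS1 (-1.11) and STC2 (-1.04) lower. With the local background correction WARS1 was at -0.27 and STC2 at -0.22, and the median of -0.05 lay below the random range. Heat shock and immediate early genes had one of -0.04 (percentile 19.62), with FOS at the upper end and IER3 (-2.13) at the lower. Under the local background correction FOS was at -0.28 and IER3 at 0.00, where another probe of IER3 was brightest and the probe used here was at 0.17. Glutathione and NRF2 genes were at 0.00 (percentile 45.02), with GPX2 and catalase CAT (1.64) higher and TXNRD1 (-1.02, and 0.39 with the local background correction) lower. Respiratory chain genes were at -0.01 (percentile 41.68) between NDUFA2 (0.55) and ATP5F1B (-0.62), and small RNA pathway genes at -0.03 (percentile 20.25) between DDX17 (0.78) and XPO5 (-0.42). Of markers of other cell types, 9 of 16 fibroblast genes were detected, with a median of -0.01 (percentile 42.81) and COL5A1 highest at 0.75. The 9 detected blood and endothelial genes had a median of 0.01 (percentile 72.87) with KDR highest at 0.32, and lay above the random range with the local background correction (0.04) and with plain local subtraction (0.57). Mean and median differed in sign for the interferon, heat shock, small RNA, fibroblast, mesenchymal and glutathione lists, with both values between -0.04 and 0.06.

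**Figure D3:**
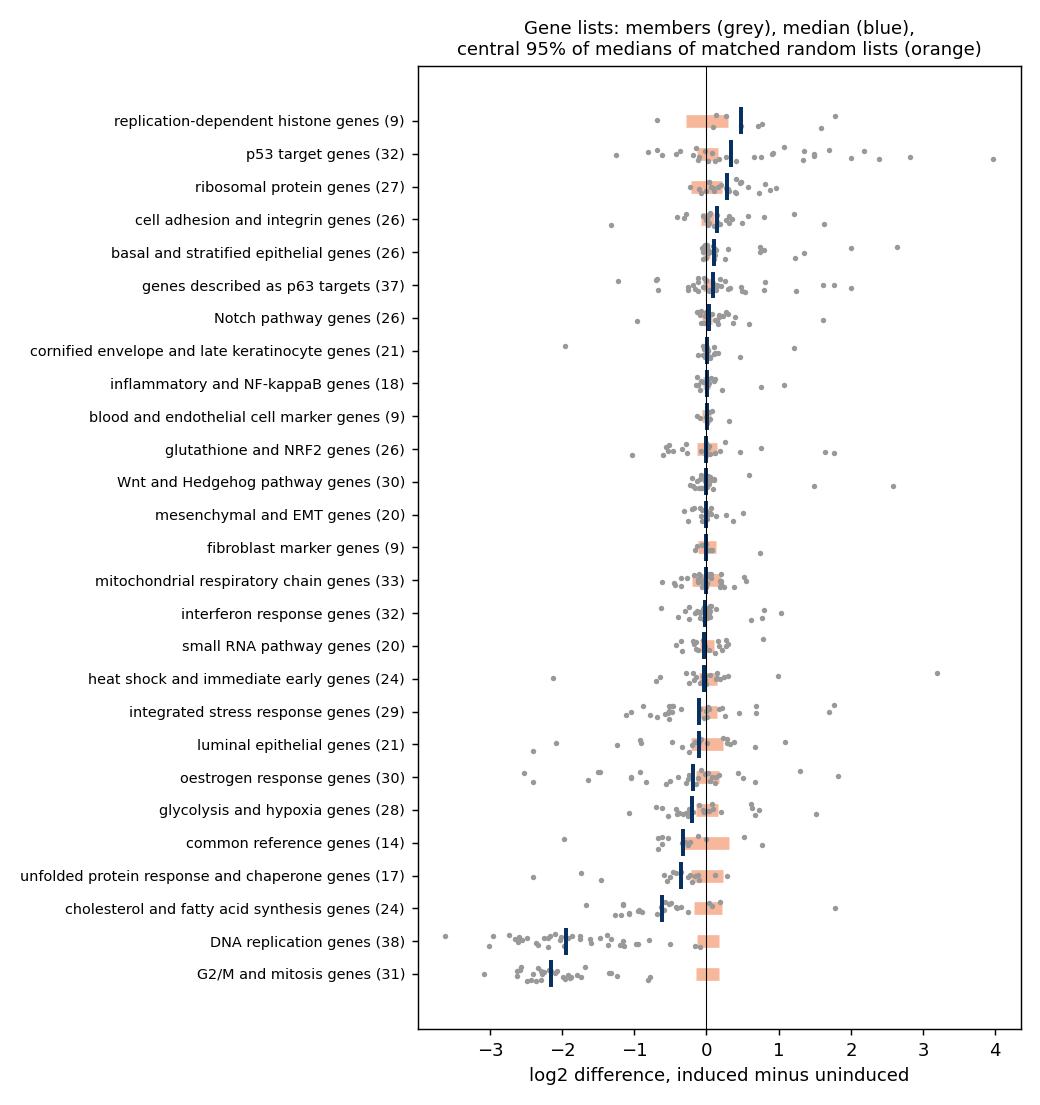
Log2 difference (induced minus uninduced) of the detected members of each of 27 gene lists (grey points, number in brackets), their median (blue bar) and the central 95% of the medians of 10000 random lists matched on signal (orange). The G2/M and DNA replication medians (-2.15 and -1.95) lie far below the random range, and the histone and p53 target medians (0.48 and 0.34) lie above it.

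Among genes detected on the induced array alone, TP63 had the largest lower bound. S100A8, a calcium-binding protein of stressed epithelium and myeloid cells, was at least 2.32-fold higher there, GDPD2 at least 1.99-fold, ANXA1, an annexin, at least 1.71-fold and GPNMB at least 1.44-fold. Of genes detected on the uninduced array alone, POLQ, the DNA polymerase theta, was at least 1.62-fold higher there, FFAR2 at least 1.57-fold, BRINP2 at least 1.56-fold, the neuropeptide NMU at least 1.41-fold and C1orf162 at least 1.38-fold. These bounds are on the scale with the offset. With the local background correction the differences of S100A8 (1.22) and GDPD2 (1.01) were 0.16 and 0.04, and GDPD2 was at 0.98 with median scaling and 0.99 with loess. No array of doxycycline-treated cells without the construct was analysed here, so differences due to doxycycline and to ΔNp63α cannot be told apart.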

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

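Tests of single probes, doxycycline, exchanged labels, mixed-in cells and histone labelling were chosen after the results had been seen. The tests of array position, of cell cycle exit genes and of members shared with the p63 lists were written down beforehand.

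Probes without a gene symbol, which no comparison above uses, also differed. Of 3576 detected, 23 (0.6%) were higher by at least 2-fold in the induced array and 27 (0.8%) were lower.

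Cell cycle genes were lower in the induced array. The tables argue against a shift of whole array blocks. The median over the 69 members was -2.03 before and after subtracting the median of each of 24 blocks, which lay between -0.07 and 0.04. A local effect within a block need not move the block's median and was not tested. They also argue against failed single probes, as 11 other detected probes of the same genes had a median of -1.87 with 10 below 0. Fewer cycling cells are a candidate explanation: 20 genes reported to rise when cells leave the cycle had a median of 0.76, above all matched random lists (central 95% from -0.15 to 0.19), with 15 of 20 above 0. Among those below 0 were the cyclin-dependent kinase inhibitor CDKN1B (-0.62) and TOB1 (-0.55). This list was not run under the alternatives. Whether ΔNp63α, doxycycline itself or a difference between single cultures such as cell density lowered them stays open, since integrated stress response genes, which a block of mitochondrial translation by doxycycline would raise, had a median of -0.10 (percentile 5.45), and this does not cover its other effects.

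The p53 target list lay above random lists, with 11 of 32 members higher by at least 1 in the induced array. Exchanged labels are argued against by the TP63 difference of 2.35 towards the array labelled induced, as far as its probe reports the construct. The probe was not detected on the uninduced array. With the planned local background correction the TP63 difference was 0.04 and with local subtraction 0.50, short of the 2-fold that the test asked for. The 30 members in neither the p63 nor the basal list had a median of 0.22 at percentile 99.41 (random range -0.13 to 0.17). The p53 list shares only 2 listed members with each of these lists, so leaving them out could change little. The value argues only against those shared members as the whole cause. Genes outside the p63 and basal lists can still be p63 targets, and this value is given for the correction on blank spots only. Basal cells mixed into the induced culture stay open: KRT5, KRT14, KRT15, KRT17 and KRT6A had a median difference of 0.12, between -0.07 for KRT6A and 0.75 for KRT15. The list's median lay above the random range under 12 of 13 alternatives, up to 0.63, and was 0.08 with the local background correction, and whether p53 activity, ΔNp63α or doxycycline is its source was not tested.

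The histone list lay above random lists matched on signal, with a median of 0.48 and 2 of 9 members higher by at least 1, while the DNA replication list lay below them. A candidate explanation is that labelling started from poly(A) tails, so that histone transcripts with tails, a minor form in cycling cells, were measured. All 9 listed histone genes with a probe (100%) were detected, which decides nothing, because no annotation of such forms was used here. Binding of near-identical copies to the same probe was not tested.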

How the results depend on the processing

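Signal over background limits the values of dim genes, whose differences the offset compressed, and no setting makes up for 1 array per group. Subtraction of the blank mean was chosen after seeing the data. No paired analysis was possible because each group holds 1 array. Of 69 named genes past 1, 69 kept their direction and stayed past 1 without background correction, with offset 16, with the blank mean and with no filter, 68 with the mean of probes, 67 with 75th percentile scaling, loess or the authors' values, and 66 with median scaling, where the others kept their direction. With normexp on the local background column, as first planned, 35 did, 25 lay within 1 and 9 reversed, and with plain local subtraction 49, 8 and 3 of 60. The cause was not tested gene by gene.

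The count of genes higher was 1251 with local subtraction, 1022 with the blank mean, 526 with offset 16 and 950 in the authors' values. The count of genes lower was 1485, 1047 and 957 with local subtraction, the blank mean and the authors' values. Subtracting a background with no offset or a smaller one widens the differences of dim genes, so more of them pass 1. Without any background correction the counts were 351 and 471. At 1.5-fold the counts were 971 and 1045 and at 4-fold 44 and 97. Other settings kept both counts within 1.5 times. Genes higher made up 42.4% of those past 1, and between 34.3% (median scaling) and 49.8% (authors' values) elsewhere.

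TP63 was at 0.04 as first planned and 0.50 with local subtraction, and between 2.3 and 6.53 under the 10 others. As first planned, genes past 1 that reversed were FOS -0.28, CDKN1A -0.47, GPX2 -0.26, JAG1 -0.27, ITGAV -0.13, KRT80 -0.05, SPDEF 0.06, FZD5 -0.51 and TXNRD1 0.39. With local subtraction they were GPX2 -2.15, KRT80 -0.38 and SPDEF 0.76. Genes within 1 also changed sign, as first planned YWHAZ 1.37, FASN 0.60, ENO1 0.55, H2BC21 -0.49 and RFC1 0.08, and with local subtraction YWHAZ 1.41, ENO1 0.56, H2BC21 -0.75, RFC1 0.04 and COL17A1 0.01. IER3 was at -0.02 with local subtraction. Of named genes within 1, 14 passed it in their direction with offset 16, 19 with the blank mean, 16 with local subtraction and 15 in the authors' values, such as NEK2 (-1.48, -2.77, -1.32 and -2.68), ANLN (-1.55, -3.06, -1.02 and -2.92) and ITGB4 (1.29, 1.84, 1.46 and 1.89). SERPINB5 reached 1.03, 2.64 and 2.74 and H1-5 -1.31, -2.42 and -2.32 in these without local subtraction. HES4 passed 1 in 7 settings (-1.15 to -1.0) and RPL10 in 3 (1.03 to 1.04). As first planned 5 did, PLK2 -2.88, RPS6 -2.35, HPRT1 -1.17, NDUFA2 4.27 and ATP5F1B -5.59.

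Medians of the G2/M, replication, histone, lipid and unfolded protein lists stayed outside the random range in all 13 alternatives. Others moved inside it, and the cause was not tested. As first planned these were p63 targets 0.03, p53 targets 0.08, adhesion 0.09, glycolysis -0.01, ribosomal 0.10 and reference genes 0.01 (reversed). With local subtraction they were basal 0.18, p63 targets 0.13, oestrogen -0.24, glycolysis 0.05 (reversed), ribosomal 0.21 and reference -0.01. In the authors' values they were basal 0.23, p63 targets 0.22, adhesion 0.23 and reference -0.39. With median, 75th percentile and loess scaling glycolysis was at -0.20, -0.15 and -0.15 and reference at -0.40, -0.34 and -0.31. With the mean of probes basal was at 0.05, p63 targets at 0.04 and reference at -0.21. The basal list was at 0.19 with the blank mean, and p63 targets at 0.03 without a filter and 0.11 above the median signal. Integrated stress response genes moved below the random range with the blank mean (-0.36), offset 16 (-0.20), the authors' values (-0.27) above the median signal (-0.48) and as first planned (-0.05), luminal genes as first planned (-0.47) and with local subtraction (-0.59), and blood and endothelial genes above it in the same settings (0.04 and 0.57).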

Other observations

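The families described here were noticed in the data and chosen after their values were seen. Many metallothioneins, which bind zinc and copper, were lower: of 11 detected members 6 were lower by at least 1 and 0 lay above 0, with a median of -1.17 (between -2.02 and -0.96 under the alternatives). The dim members MT1A (-0.20), MT1DP (-0.02), MT1E (-0.01) and MT1M (-0.01) lay near 0. MT2A had deposited intensities of 5380.8 in the uninduced and 968.0 in the induced array. Near-identical copies make the single members uncertain. Among 18 alpha and beta tubulins 6 were lower by at least 1 and 0 higher, with TUBA1B at -2.58, TUBB at -1.97 and TUBB4B at -1.50, although the family's median was only -0.11 (-0.93 to -0.02). TUBA1A, at 0.72, went the other way.

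The 4 ID genes, inhibitors of basic helix-loop-helix transcription factors, all lay above 0, with ID3 at 3.65, ID1 at 2.24 and ID2 at 1.61 and a median of 1.93 (1.40 to 2.52). Of the 4 YPEL genes 2 were higher by at least 1, YPEL5 (2.36) and YPEL2 (2.31), with a family median of 1.42 (0.58 to 2.31). The 6 GABARAP and MAP1LC3 genes, which act in autophagosome formation, had a median of 0.73 (0.36 to 0.85), with MAP1LC3B at 1.30. Annexins were mixed, with ANXA8L1 (2.46) and ANXA2 (1.97) higher, ANXA6 (-1.14) lower and a median of 0.24 (0.19 to 0.59) over 12 members.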
